A study of Homo sapiens with 25 samples.

How the data were processed

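RNA was measured in A549 cells, an established human lung carcinoma line, that carry an auxin-inducible degron tag (mAID) on TRRAP, a scaffold subunit of the SAGA and TIP60 histone acetyltransferase complexes. The series title names TRRAP, the transcription of mitotic genes by the MMB complex (B-MYB bound to the MuvB core) and sensitivity to CHK1 inhibition. Per the labels, cells were held in 2 mM thymidine for 20 h and released for 4 h. The compound 5-Ph-IAA at 1 µM for 6 h was used to degrade TRRAP, and prexasertib, an inhibitor of the checkpoint kinase CHK1, was given for 3 h. The RNA labels give the prexasertib dose as 100 mM, whereas the labels of the chromatin samples give it in nM, so no dose is used here. The labels also give the genotype as WT beside a growth protocol that names the mAID-TRRAP cells, and the grouping follows the sample titles. There were 4 groups of 3 libraries: DMSO, prexasertib, 5-Ph-IAA and both drugs. The 13 CUT&RUN samples of the series are not analysed here.

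The RNA libraries were poly(A)-selected and directional. The deposited table holds raw counts per gene, whole numbers with 1 column per library, which the authors had not normalized. The submitters' processing notes name featureCounts 2.0.8, limma 3.58.1 and the build hg38. Bowtie2 2.5.3 is also named among the tools of the series, but the aligner, the annotation and the strand setting of the RNA counts are not given in the sources used here. Genes that overlap another gene on the opposite strand, close paralogs and genes inside other genes are therefore reported as uncertain. Of 28395 numeric gene IDs in the table, 27745 matched the reference gene table, and the other 650 held 0.0324% of the counts. Total counts per library ran from 10830048 to 17789482. Between 17135 and 18912 genes had a count, and the 10 most abundant genes of a library held 5.1% to 5.73% of its counts. Counting intervals and floors would cover counting error only, since reads without molecular identifiers are not independent molecules.

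Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr on the groups (minimum count 10, minimum total 15), which left 14658 genes with 99.92% of the counts. Libraries were scaled by TMM factors, which lay between 0.925 and 0.978 without 5-Ph-IAA and between 1.02 and 1.1 with it. A robust quasi-likelihood model with a term for each group was fitted to all 12 libraries, and its F-test gave each comparison. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called at an adjusted p under 0.05. All adjusted p-values for single genes come from this edgeR test unless another tool is named. The standard error (SE) printed with a log2 fold change is its size divided by the square root of F. Levels are CPM, the scaled counts that edgeR's cpm function gives on TMM-adjusted library sizes, written as mean ± SD over 3 libraries. The levels of the markers of other cell types are the exception and used library size alone. Log2 CPM used a prior count of 2. The biological coefficient of variation was 12.8%. The p-values measure the spread between these samples, because the labels do not say whether the libraries came from separate cultures.

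The comparisons were prexasertib against DMSO, 5-Ph-IAA against DMSO, both drugs against prexasertib, both drugs against 5-Ph-IAA, both drugs against DMSO, and the interaction of the 2 drugs on the log scale. The 18 gene lists, the rule for named genes and the tests were fixed before the data were examined. The lists were MMB targets, E2F targets, p53 targets, MYC targets, TRRAP complexes, MuvB and CDK control, immediate-early genes, ATF4 targets, NF-kB and interferon genes, NRF2 targets, sterol genes, AHR targets, DNA repair genes, replication-dependent histones, ribosomal proteins, epithelial markers, mitochondrial mRNAs and other cell type markers. The mitochondrial list had 0 of 13 genes in the table and was not analysed here. The list of markers of blood cells, fibroblasts, endothelium and neurons had 4 of 16 genes tested, fewer than the 5 required, and is given by level. Lists were tested with camera of limma 3.58.1 on log2 CPM with a preset correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry were run beside it. The MMB score of a library is the mean log2 CPM of the MMB targets, compared by exact two-sided permutation within the arms of the other drug (400 arrangements, smallest p 0.005). Within 1 pair of groups, 3 libraries against 3 cannot give an exact p below 0.1.

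The named genes were the 6 with the largest log2 fold change in each direction. These had to be called, with a mean log2 CPM of at least 1, a gene symbol, and all 3 libraries of one group above all 3 of the other. For each list with at least 3 called members, the 2 with the smallest adjusted p in the main direction and the 1 in the other direction were added. TRRAP, MYBL2, LIN9, FOXM1, CHEK1, CCNB1, PLK1, CDKN1A and MYC were always named. For both drugs against 5-Ph-IAA the top genes were left out. Any other gene named as a list member was chosen after its values were seen.

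The labels number the replicates 1 to 3 in every group without saying what a number stands for. After the group means were removed, libraries with the same number correlated across genes in all 18 pairs, with r from 0.22 to 0.63, so the numbers were taken to pair the samples. Libraries numbered 3 stood apart, with r between -0.5 and -0.33 to numbers 1 and 2, while numbers 1 and 2 correlated at 0.2 to 0.37. The median r was 0.25 within number 1, 0.34 within number 2 and 0.27 between them, although 10 of the 12 libraries correlated best with their own number. The correlations therefore separate number 3 from the others and do not clearly pair the libraries numbered 1 and 2. The first principal components held 34.1%, 23.5% and 13.9% of the variance. With the replicate number as a block, the coefficient of variation was 5.72%. Blocked values are printed for the counts over all genes and for selected lists and genes. The alternatives tried were DESeq2 1.42.0 with its Wald test, limma-voom, size factors of the DESeq2 kind, library size without scaling factors, no low-count filter, and a filter of at least 5 CPM in 3 libraries. Fits with only the compared groups, the replicate block, each library left out in turn, and a minimum log2 fold change of 1 were also made. Fits without the 4 libraries numbered 3 were added after the data were seen. They rest on the libraries numbered 1 and 2 alone, and number 2 differed from number 1 at only 5 higher and 10 lower genes. Their p-values and counts therefore do not measure the spread that number 3 adds.

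The fits were tested on simulated data of 14658 genes, of which 68 were changed by 0.5, 66 by 1 and 66 by 2 on the log2 scale. With the replicate structure of these libraries simulated, the group model recovered 36.8%, 80.3% and 92.4% of these in a comparison of a pair of groups. The same sizes were recovered at 10.3%, 54.5% and 86.4% for the interaction. With the replicate block, recovery of the interaction was 60.3%, 87.9% and 98.5%, and 11 of 175 calls were false. The simulated counts used the spread and the additive replicate effects of the blocked fit itself, so its rates need not hold for the real libraries. Only genes above a minimum mean count were changed, so the rates do not cover weaker genes.

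Results for 3 genes are not reported here, so a list of genes in the text may be shorter than its count.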

Results

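The data are RNA counts from 12 libraries of A549 cells with degron-tagged TRRAP, all synchronized with thymidine and released for 4 h, which the series design text describes as S-phase cells. Each of the 4 groups (DMSO, prexasertib, 5-Ph-IAA and both drugs) had 3 libraries, with total counts per library from 10830048 to 17789482. The epithelial keratins and other fixed epithelial markers were measured in all groups. Of the fixed markers of other cell types, COL1A1 had a mean of 31.7 CPM, SNAP25 48.4 CPM and SYT1 8.96 CPM over the 12 libraries, and no other gene of that list exceeded 0.748 CPM (COL3A1). These marker levels used library size without the TMM factors. On that scale the group means of COL1A1 lay between 30.6 and 32.5 CPM and those of SNAP25 between 47.4 and 49 CPM. Those of SYT1 lay between 7.64 (DMSO) and 10.1 CPM (prexasertib), and those of COL3A1 between 0.345 (prexasertib) and 1.29 CPM (5-Ph-IAA). The TMM factors were 0.925 to 0.978 without 5-Ph-IAA and 1.02 to 1.1 with it. On the TMM scale the groups with 5-Ph-IAA would therefore lie lower relative to the others.

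TRRAP (NCBI Gene 8295, hg38 chromosome 7, 98878532 to 99013241) is the target of the degron, which acts on the protein, so its mRNA does not check the labels. TRRAP mRNA stood at 83.2 ± 9.9 CPM in DMSO, 74.8 ± 10.4 CPM with prexasertib, 133 ± 15.3 CPM with 5-Ph-IAA and 119 ± 20.8 CPM with both drugs (SD, n = 3). It rose with 5-Ph-IAA by 0.67 ± 0.14 (log2, SE; edgeR adjusted p = 0.0042), and by 0.67 ± 0.14 under prexasertib (edgeR adjusted p = 0.0054). The change with prexasertib alone was -0.15 ± 0.14 (edgeR adjusted p = 0.67).

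Genes of the G2/M program, known as targets of the B-MYB-MuvB and FOXM1 complexes, moved in opposite directions with the 2 drugs. The mean log2 CPM of the 71 MMB targets was 7.23 ± 0.019 in DMSO, 7.78 ± 0.018 with prexasertib, 6.36 ± 0.016 with 5-Ph-IAA and 6.9 ± 0.016 with both drugs (SD, n = 3). It fell by 0.868 with 5-Ph-IAA without prexasertib and fell by 0.875 with prexasertib present (mean -0.872, exact two-sided permutation p = 0.005, the smallest possible). Prexasertib raised it by 0.544 without 5-Ph-IAA and by 0.537 with it (mean 0.54, exact two-sided permutation p = 0.005). The difference between these effects was -0.00712, and the 3 replicate numbers gave -0.021, 0.027 and -0.028. With library size alone as the scaling, the effects were -0.724 and 0.496. KIF20A, a mitotic kinesin needed for cytokinesis (NCBI Gene 10112, chromosome 5, 138179112 to 138187723), had 215 ± 5.23 CPM in DMSO and 486 ± 17.8 CPM with prexasertib. Its level was 67 ± 1.89 CPM with 5-Ph-IAA and 200.2 ± 2.66 CPM with both drugs.

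**Figure D1:**
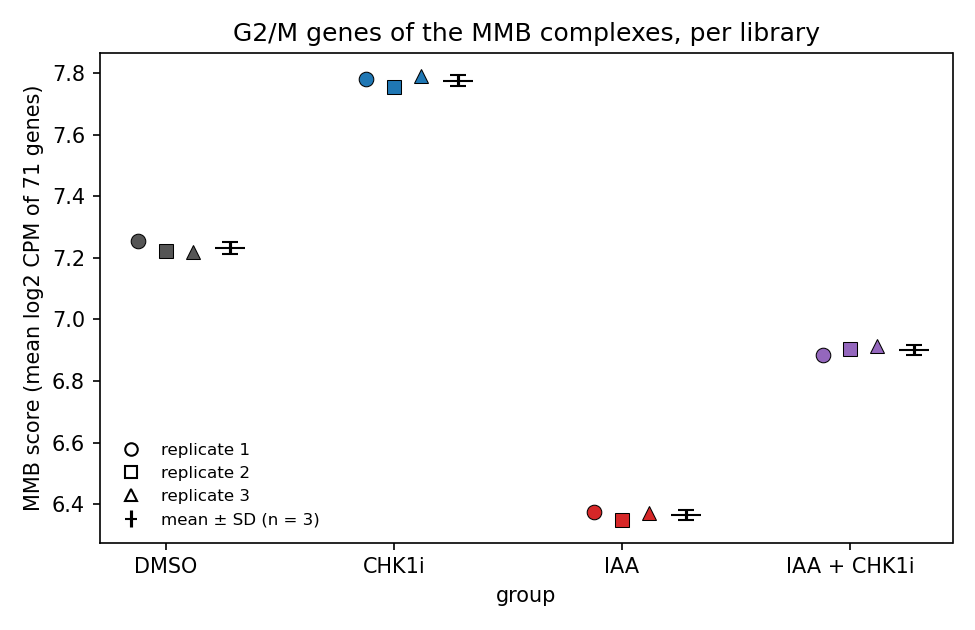
Mean log2 CPM of the 71 MMB targets in each of the 12 libraries, by group, with the mean and SD of the 3 libraries beside the points. The 3 libraries of each group lie within 0.04 of each other, from 6.35 to 6.38 with 5-Ph-IAA and from 7.76 to 7.79 with prexasertib.

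Prexasertib against DMSO asks what the CHK1 inhibitor did without 5-Ph-IAA. Mitotic genes rose: 52 of 71 MMB targets were higher and 0 were lower (63 higher and 1 lower adjusted over the list alone), with a median log2 fold change of 0.54. KIF20A rose by 1.17 ± 0.059 (SE) and the centrosomal kinase gene NEK2 by 0.99 ± 0.076. CCNB1, the cyclin that activates CDK1, rose from 526 ± 33.3 to 856 ± 18 CPM (0.70 ± 0.087). PLK1, the polo-like kinase of mitotic entry, rose from 337 ± 23.4 to 481 ± 50.8 CPM (0.51 ± 0.085). The edgeR adjusted p-values of these 4 genes were 2.9e-07, 2.4e-05, 0.00051 and 0.0038. The MMB list passed camera with adjusted p = 1.28e-49 and with an estimated correlation (adjusted p = 0.00022). The replicate block gave 66 higher MMB targets and 2 lower.

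Most called genes of S phase were lower. Of 46 E2F targets 15 were lower and 1 was higher (26 lower and 1 higher adjusted over the list alone; 28 lower with the replicate block), with a median of -0.34. CHAF1A, a chromatin assembly factor, fell by 0.64 ± 0.085 and UHRF1, which maintains DNA methylation, fell by 0.67 ± 0.09, while PCNA, the sliding clamp of DNA polymerase, rose by 0.33 ± 0.077 to 1020 ± 53.2 CPM. For the E2F list camera gave adjusted p = 1.11e-13, and adjusted p = 0.17 with an estimated correlation (0.045 with the replicate block as well). Of 25 DNA repair genes 5 were lower and 1 was higher (10 and 1 adjusted over the list alone; 12 lower with the replicate block), with a median of -0.26 and camera adjusted p = 1.7e-05 (0.011 with an estimated correlation). TOPBP1, which activates the ATR kinase, fell by 0.45 ± 0.074, BRCA1 fell by 0.32 ± 0.065, and the checkpoint adaptor gene MDC1 rose by 0.42 ± 0.099. RAD54L, XRCC2 and BLM made up the rest of the 5 lower repair genes. That count moved by more than 1.5 times without DMSO replicate 2 or 3, prexasertib replicate 1, 2 or 3, or 5-Ph-IAA replicate 1 or 2, down to 1 without prexasertib replicate 1. In the MuvB and CDK control list, RBL1, which encodes the DREAM subunit p107, fell by 1.05 ± 0.078 (edgeR adjusted p = 2.2e-05) and LIN54 fell by 0.60. CDC25C rose by 0.58 ± 0.12, CCNA2 by 0.42 ± 0.098 and WEE1 by 0.43. That list as a whole gave a median of 0.01, negative with library size as the only scaling (camera adjusted p = 0.871).

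Most called immediate-early genes and p53 targets were higher. EGR1, a rapidly induced transcription factor (NCBI Gene 1958), rose from 2.78 ± 1.67 to 38.6 ± 15.7 CPM, a log2 fold change of 3.80 ± 0.44 (edgeR adjusted p = 0.00084). FOSB rose by 3.14 ± 0.71 and NR4A1 by 1.22 ± 0.096, and KLF6 fell by 0.53 ± 0.083. In the immediate-early list 7 of 24 tested genes were higher and 1 was lower (14 and 2 adjusted over the list alone; 15 and 2 with the replicate block), with a median of 0.43. This list had camera adjusted p = 3.12e-05, and adjusted p = 0.17 with an estimated correlation. Of 28 p53 targets 14 were higher and 1 was lower (15 and 1 adjusted over the list alone; 21 higher with the replicate block), with a median of 0.32 and camera adjusted p = 6.32e-12. With an estimated correlation the p53 list gave adjusted p = 0.1 (0.045 with the replicate block as well). Without prexasertib replicate 1 or DMSO replicate 3 the higher p53 targets fell to as few as 8, and without DMSO replicate 1 or prexasertib replicate 1 or 2 the higher immediate-early genes fell to as few as 4. CDKN1A, the inhibitor of cyclin-dependent kinases p21, rose from 1126 ± 82.5 to 1506 ± 108 CPM (0.42 ± 0.083). The antiproliferative gene BTG2 rose by 0.97 ± 0.11 and the secreted factor gene GDF15 by 0.67 ± 0.081, while ZMAT3, which encodes an RNA-binding protein, fell by 0.81 ± 0.17.

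Replication-dependent histone genes, whose normal mRNA ends in a stem-loop in place of a poly(A) tail, rose in 9 of 18 tested members and fell in 0 (12 and 0 adjusted over the list alone), with a median of 1.05. The histone list had camera adjusted p = 3.94e-14 (0.0022 with an estimated correlation). H2BC12 rose by 1.02 ± 0.11 and the linker histone gene H1-2 by 0.97 ± 0.12. H3C10 rose by 1.96 ± 0.27. Histone genes are close paralogs and were captured here from poly(A)-selected RNA, so their single values are uncertain. Of the 68 histone genes in the table only 18 passed the count filter. Some of these were weak, such as H3C2 (mean 0.994 CPM) and H3C12 (mean 0.659 CPM). A weak gene can pass the filter through the group where it is high, which can raise the median and the camera result of the list. Other large rises were those of APOLD1 (2.40 ± 0.28) and the immune checkpoint gene LAG3 (1.80 ± 0.43). Among genes that meet the rule for named genes (mean log2 CPM of at least 1), the largest falls were CCDC183-AS1 (-1.66 ± 0.37), HLX (-1.39 ± 0.22), the Wnt ligand gene WNT6 (-1.37 ± 0.18), PPARGC1B (-1.36 ± 0.32), UBE2QL1 (-1.31 ± 0.22) and the noncoding RNA MILIP (-1.27 ± 0.14). CCDC183-AS1 is an antisense gene, so its value is uncertain. The remaining lists had few calls. ATF4 rose and its target STC2 fell. BRD8 rose and EPC2 fell among the TRRAP complexes, OAS1 fell among the interferon genes, HMOX1 fell among NRF2 targets (list camera adjusted p = 0.132, and 0.011 with the replicate block, against 0.59 with the block and an estimated correlation), and IDI1 rose among sterol genes. In the MYC, AHR, ribosomal and epithelial lists edgeR called 0 genes. At an unadjusted p under 0.05 there were 4, 1, 0 and 1, DESeq2 called 0, 1, 0 and 1, and limma-voom 0 in each. Ribosomal proteins had a median of 0.08 (camera adjusted p = 0.0467, and 0.94 with an estimated correlation; the call was lost without DMSO replicate 1 at 0.112, DMSO replicate 2 at 0.529, prexasertib replicate 3 at 0.816 or replicate 2 of both drugs at 0.052).

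TRRAP, MYBL2 (-0.10 ± 0.16), LIN9 (0.04 ± 0.13), FOXM1 (0.13 ± 0.091), CHEK1 (-0.09 ± 0.088) and MYC (-0.07 ± 0.1) were not called (edgeR adjusted p between 0.55 and 0.94). Over all genes, edgeR called 346 higher and 347 lower. With the replicate block the counts were 1227 and 1432, without the libraries numbered 3 they were 1060 and 1030, and 91.6% of those calls had the same sign in the libraries numbered 3. Leaving out 1 library gave 183 to 385 higher and 123 to 401 lower, with both lowest counts without prexasertib replicate 1. The counts also moved by more than 1.5 times without prexasertib replicate 2 or DMSO replicate 1 or 2, and the lower count without DMSO replicate 3. Library size as the only scaling made 37.3% of calls higher instead of 49.9%. The calls of FOSB (8 of 12 libraries, edgeR adjusted p up to 0.12), LAG3 (5, up to 0.13), CCDC183-AS1, PCNA and MDC1 (5 each), PPARGC1B, ZMAT3 and CCNA2 (4 each) and CDC25C (DMSO replicate 1 or 2) were lost on leaving out single libraries. BRCA1 (0.079) and CDKN1A (0.064) lost theirs without prexasertib replicate 1.

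5-Ph-IAA against DMSO asks what the compound used to degrade TRRAP did without prexasertib. TRRAP protein, and 5-Ph-IAA in cells without the degron, are not analysed here. Mitotic genes fell: 66 of 71 MMB targets were lower and 0 were higher (67 and 0 adjusted over the list alone), with a median log2 fold change of -0.85. KIF20A fell by 1.68 ± 0.06 (SE), and TACC3, a spindle protein gene, from 193 ± 3.12 to 83.6 ± 3.56 CPM (-1.21 ± 0.064). CCNB1 fell from 526 ± 33.3 to 241 ± 27.7 CPM (-1.12 ± 0.088) and PLK1 from 337 ± 23.4 to 139 ± 9.75 CPM (-1.28 ± 0.087). The edgeR adjusted p-values were 3.7e-09, 2.9e-07, 2.4e-06 and 9.9e-07. Camera gave adjusted p = 2.98e-44 for the list, and adjusted p = 0.00033 with an estimated correlation.

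Most S-phase and growth genes tested were lower as well. Of 46 E2F targets 29 were lower and 0 were higher (39 and 0 adjusted over the list alone), with a median of -0.51. Their camera test gave adjusted p = 8.73e-15, and adjusted p = 0.12 with an estimated correlation (0.031 with the replicate block as well). RRM2, a subunit of ribonucleotide reductase, fell from 462 ± 53.4 to 125 ± 22.1 CPM (-1.89 ± 0.14), and CDCA7 fell by 1.32 ± 0.096. Of 48 MYC targets, which are growth and ribosome biogenesis genes, 37 were lower and 0 were higher (39 and 0 adjusted over the list alone), with a median of -0.59. The nucleolar genes GNL3 and NOP56 fell by 1.16 ± 0.082 and fell by 0.85 ± 0.066. For the MYC list camera gave adjusted p = 1.09e-18, and adjusted p = 0.078 with an estimated correlation (0.00083 with the replicate block as well). MYC mRNA itself rose by 0.36 ± 0.1 (edgeR adjusted p = 0.02). Of 22 genes for MuvB and CDK control 13 were lower (15 adjusted over the list alone), with a median of -0.31, camera adjusted p = 1.2e-05 and 0.027 with an estimated correlation. This list shares 5 genes with other lists, among them CDC25B and CCNA2 with the MMB targets, and was not tested without them. CDC25B, a phosphatase that activates CDK1, fell from 600.1 ± 13.8 to 324 ± 17.3 CPM (-0.89 ± 0.071) and the cyclin gene CCNA2 fell by 1.02 ± 0.1. FOXM1 fell by 0.43 ± 0.091 (edgeR adjusted p = 0.0048) and CHEK1 fell by 0.32 ± 0.088 (edgeR adjusted p = 0.019). MYBL2, which encodes B-MYB, had a value of -0.42 ± 0.16 with edgeR adjusted p = 0.092, and was called with the replicate block (3.9e-08). LIN9 had 0.02 ± 0.13 (edgeR adjusted p = 0.93).

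Of 28 p53 targets 10 were lower and 0 were higher (13 and 0 adjusted over the list alone; 21 lower with the replicate block), with a median of -0.28, camera adjusted p = 1.48e-05 and adjusted p = 0.2 with an estimated correlation. The apoptosis genes AEN and PHLDA3 fell by 0.48 ± 0.059 and fell by 0.55 ± 0.073. CDKN1A had a value of -0.16 ± 0.083 (edgeR adjusted p = 0.19, and 0.0041 with the replicate block). Of 20 ATF4 targets 6 were lower (7 adjusted over the list alone; 13 with the replicate block), with a median of -0.28, camera adjusted p = 0.000834 and adjusted p = 0.078 with an estimated correlation. Without 5-Ph-IAA replicate 3 the count was 10. ATF4 fell by 0.66 ± 0.072 and the secreted hormone gene STC2 fell by 0.83 ± 0.079. Replication-dependent histones rose in 6 of 18 members (6 adjusted over the list alone), with a median of 0.60, camera adjusted p = 0.00421 and adjusted p = 0.12 with an estimated correlation. With library size as the only scaling the histone list gave camera adjusted p = 0.0548. Without DMSO replicate 2 or 5-Ph-IAA replicate 1 or 2, as few as 2 histones were called. H2BC12 rose by 0.63 ± 0.11 and H1-2 by 0.55 ± 0.12.

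Other lists went both ways. Among TRRAP complexes 6 were higher and 4 lower, with a median of -0.02 that was positive with library size as the only scaling (camera adjusted p = 0.653). DMAP1 of the TIP60 complex rose by 0.53 ± 0.11 and BRD8 of the same complex fell by 0.52 ± 0.084. USP22, RUVBL1 and MORF4L1 were the other 3 lower genes, and without DMSO replicate 1 or 5-Ph-IAA replicate 2 as few as 2 were higher. In the immediate-early list CCN2, a matricellular protein gene, rose by 0.97 ± 0.11, NR4A1 rose by 0.43 ± 0.096, and IER5 fell by 0.52 ± 0.079 (4 higher and 2 lower in all, as few as 2 higher without DMSO replicate 2 or 5-Ph-IAA replicate 1 or 3, camera adjusted p = 0.417). Among NF-kB and interferon genes IRF1 fell by 0.45 ± 0.077, SOD2 fell by 0.38 ± 0.093 and IRF7 rose by 0.77 ± 0.18 (2 higher and 5 lower, camera adjusted p = 0.184). Without DMSO replicate 2 or 3 or 5-Ph-IAA replicate 1 or 2 as few as 1 of them was lower, and without 5-Ph-IAA replicate 3 the list passed at 0.0447 (0.7 with an estimated correlation on all libraries). NRF2 targets had 3 lower genes (10 with the replicate block) and a median of -0.18 (camera adjusted p = 0.0191, and 0.17 with an estimated correlation; 0.117 with library size as the only scaling, 0.0766 with the strict filter and 0.0614 without DMSO replicate 3). AKR1C3 fell by 0.50 ± 0.12 and AKR1B10 by 0.31 ± 0.073, both close paralogs whose reads can be shared. The sterol genes SC5D (0.63 ± 0.16) and IDI1 (0.32 ± 0.094) rose, and FDPS (-0.32 ± 0.083) and SQLE (-0.37) fell. DNA repair genes had 7 lower and 1 higher member and a median of -0.14, positive with library size as the only scaling. Their camera adjusted p was 0.0274, against 0.12 with an estimated correlation, 0.122 with library size as the only scaling, 0.0729 with the replicate block and 0.0614 without DMSO replicate 3. Among them FANCA fell by 0.61 ± 0.1 and NBN rose by 0.21 ± 0.071. Ribosomal proteins had a median of -0.17 with 0 genes called by edgeR, DESeq2 and limma-voom and 4 at an unadjusted p under 0.05 (camera adjusted p = 0.00376, and 0.71 with an estimated correlation; 0.0678 without DMSO replicate 3 and 0.09 without 5-Ph-IAA replicate 2). The replicate block gave 26 lower ribosomal genes. KRT7 and KRT8 were lower among epithelial markers (median -0.26, camera adjusted p = 0.184, and 0.026 with the replicate block, against 0.25 with the block and an estimated correlation). Of the AHR targets CYP1A1 alone was called, at 0.82 higher (edgeR adjusted p = 0.0112).

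Among genes that meet the rule for named genes, the largest rises were STON1 (2.31 ± 0.33), FBXW10 (2.18 ± 0.37), the sarcomere gene MYPN (2.04 ± 0.17), the neuronal splicing factor gene NOVA2 (1.85 ± 0.38), ATP1B2 (1.85 ± 0.38) and the gluconeogenic gene PCK1 (1.78 ± 0.42). MYPN went from 5.07 ± 1.04 to 20.8 ± 1.16 CPM. STON1 and FBXW10 overlap neighbouring genes or have close paralogs and are uncertain. By the same rule the largest falls were the DNA helicase gene PIF1 (-2.27 ± 0.23), SNHG4 (-2.25 ± 0.28), SNORD104 (-2.21 ± 0.25), the MYC-network repressor gene MXD3 (-1.97 ± 0.16), RRM2 and SNHG15 (-1.85 ± 0.18). SNORD104 lies inside a host gene, and its reads can belong to the host RNA. Over all genes, edgeR called 1414 higher and 1787 lower, and 2780 and 3465 with the replicate block. Without the libraries numbered 3 the counts were 2459 and 2824, and 93.9% of those calls had the same sign in the libraries numbered 3. Changes with 5-Ph-IAA are relative to the TMM scaling. With library size as the only scaling the median of all genes was 0.16 higher, and 75.4% of calls were higher instead of 44.2%. The higher count fell to 844 without 5-Ph-IAA replicate 2 and also moved by more than 1.5 times without 5-Ph-IAA replicate 1. The calls of NBN (8 of 12 libraries, edgeR adjusted p up to 0.15), IDI1 and MYC (4 each, up to 0.097 and 0.095), FDPS and CHEK1 (3 each), SC5D (without DMSO replicate 3) and SOD2 (without 5-Ph-IAA replicate 1) were lost on leaving out single libraries. MYBL2 was called without 5-Ph-IAA replicate 3 (0.045). CHEK1 (-0.161, edgeR adjusted p = 0.2), SOD2 (-0.219, 0.075), AKR1C3 (-0.339, 0.067), AKR1B10 (-0.149, 0.16) and FDPS (-0.159, 0.12) lost their calls with library size as the only scaling. Only the groups compared gave 0.062 for CHEK1 and 0.075 for NBN.

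Both drugs against prexasertib asks what 5-Ph-IAA did with prexasertib present. Mitotic genes fell here too: 68 of 71 MMB targets were lower and 0 were higher (70 and 0 adjusted over the list alone), with a median of -0.84. KIF20A fell by 1.28 ± 0.059 (SE), TACC3 fell by 1.13 ± 0.063, and PIMREG, a regulator of the metaphase-anaphase transition, fell from 176 ± 14.2 to 48.6 ± 4.11 CPM (-1.85 ± 0.1). CCNB1 fell from 856 ± 18 to 524 ± 36.4 CPM (-0.71 ± 0.087) and PLK1 from 481 ± 50.8 to 266 ± 9.46 CPM (-0.85 ± 0.086). The edgeR adjusted p-values of these 5 genes were 9.8e-08, 2.4e-07, 2.4e-07, 0.00011 and 2.2e-05. Camera gave adjusted p = 1.03e-50, and adjusted p = 0.0002 with an estimated correlation.

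E2F targets fell in 27 of 46 members and rose in 0 (31 and 0 adjusted over the list alone), with a median of -0.47, camera adjusted p = 1.27e-14 and adjusted p = 0.15 with an estimated correlation (0.029 with the replicate block as well). RRM2 fell by 1.70 ± 0.14, E2F8 fell by 1.69 ± 0.17 and CDCA7 fell by 1.29 ± 0.098. MYC targets fell in 29 of 48 members and rose in 0 (38 and 0 adjusted over the list alone), with a median of -0.50, camera adjusted p = 1.36e-16 and adjusted p = 0.081 with an estimated correlation (0.00089 with the replicate block as well). GNL3 fell by 1.15 ± 0.082 and the ribosome biogenesis gene WDR43 fell by 1.00 ± 0.077. MuvB and CDK control genes fell in 12 of 22 members (12 adjusted over the list alone), with a median of -0.35, camera adjusted p = 6.11e-06 and 0.023 with an estimated correlation. CDC25B fell by 0.84 ± 0.071, CCNA2 by 1.07 ± 0.099, FOXM1 by 0.48 ± 0.091 and CHEK1 by 0.56 ± 0.09. MYBL2 had a value of -0.35 ± 0.16 (edgeR adjusted p = 0.17, and 2.5e-06 with the replicate block). LIN9 had -0.22 ± 0.13 and MYC -0.17 ± 0.1 (edgeR adjusted p = 0.27 for each). CDKN1A had a value of 0.18 ± 0.083 (edgeR adjusted p = 0.15, and 0.0011 with the replicate block).

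ATF4 targets had 5 lower genes (8 adjusted over the list alone or without prexasertib replicate 3; 11 with the replicate block), among them ATF4 (-0.62 ± 0.072) and STC2 (-0.59 ± 0.081), with a median of -0.25, camera adjusted p = 0.00026 and adjusted p = 0.064 with an estimated correlation. DNA repair genes had 7 lower members (8 adjusted over the list alone) and a median of -0.12 that was positive with library size as the only scaling. Their camera adjusted p was 0.00508, against 0.064 with an estimated correlation. BARD1, the partner of BRCA1, fell by 0.82 ± 0.12. Among p53 targets CCNG1 (-0.40 ± 0.077), BTG2 (-0.48 ± 0.11), TP53I3, TIGAR and POLH fell. Without prexasertib replicate 1 or 2 or any 1 replicate of both drugs, as few as 2 were called. The p53 list as a whole gave a median of -0.06, positive with library size as the only scaling (camera adjusted p = 0.136). The immediate-early genes IER2 (-0.65 ± 0.12), KLF10 (-0.57 ± 0.11) and DUSP5 fell, and CCN2 rose by 0.84 ± 0.11 (list camera adjusted p = 0.157, 0.0199 without prexasertib replicate 3, and 0.7 with an estimated correlation on all libraries). Within the TRRAP complexes DMAP1 (0.56 ± 0.11), SUPT7L, TAF6L and TRRAP rose, and BRD8 (-0.59 ± 0.083), USP22 and MORF4L1 fell (list camera adjusted p = 0.97). In the histones (median -0.21), NRF2 targets, ribosomal proteins and epithelial markers edgeR called 0 genes (camera adjusted p = 0.458, 0.118, 0.118 and 0.15). At an unadjusted p under 0.05 there were 1, 4, 0 and 1, DESeq2 called 0, 4, 0 and 1, and limma-voom 0 in each. With the replicate block ribosomal and epithelial genes passed camera at 0.011 and 0.024 (0.71 and 0.25 with an estimated correlation as well), with medians of -0.08 and -0.22 without it, and library size as the only scaling made the ribosomal and NRF2 medians positive. The ribosomal list also passed without prexasertib replicate 2 (0.00858) or replicate 3 of both drugs (0.00216), and the epithelial list without prexasertib replicate 3 (0.036), while with an estimated correlation on all libraries they had 0.81 and 0.7. IRF7 rose and IRF1 fell among NF-kB and interferon genes, SQLE fell among sterol genes, and CYP1A1 and ALDH3A1 rose among AHR targets (camera adjusted p = 0.118, 0.97 and 0.576, the first 0.0363 without replicate 3 of both drugs, 0.0441 with library size as the only scaling and 0.64 with an estimated correlation).

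Among genes that meet the rule for named genes, the largest rises were PCK1 (2.53 ± 0.43), STON1 (2.32 ± 0.33), the chemokine receptor gene CCR4 (2.02 ± 0.47), TRIM55 (1.87 ± 0.29), CHST6 (1.86 ± 0.46) and FBXW10 (1.75 ± 0.33). By the same rule the largest falls were MXD3 (-1.91 ± 0.16), PIMREG, SNHG4 (-1.76 ± 0.28), RRM2, E2F8 and SAPCD2 (-1.56 ± 0.085). Over all genes, edgeR called 1150 higher and 1524 lower, and 2528 and 2913 with the replicate block. Without the libraries numbered 3 the counts were 1933 and 2559, and 92.9% of those calls had the same sign in the libraries numbered 3. With library size as the only scaling the median of all genes was 0.15 higher, and 74.3% of calls were higher instead of 43%. The higher count fell to 692 without replicate 2 of both drugs, and also moved by more than 1.5 times without replicate 1 of both drugs or prexasertib replicate 1 or 2. CHST6 lost its call without prexasertib replicate 1 or 3 or replicate 2 of both drugs (edgeR adjusted p up to 0.069).

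The effects of 5-Ph-IAA with and without prexasertib share no library, so they can be set side by side. Across 14658 genes Pearson's r was 0.739 and Spearman's rho 0.745, although genes are not independent replicates. The r was 0.231 without the low-count filter and 0.852 at 5 CPM or more. Of the called genes 754 were higher in both arms, against 111 by chance, 1199 were lower in both, against 186 by chance, and 0 had opposite directions. Genes called higher without prexasertib had a median effect of 0.57 there and 0.45 with prexasertib, and those called lower had -0.48 and -0.41. Because the genes were chosen by their calls in the first arm, a smaller median in the second can come from that choice alone. These medians therefore do not show a weaker effect with prexasertib.

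**Figure D2:**
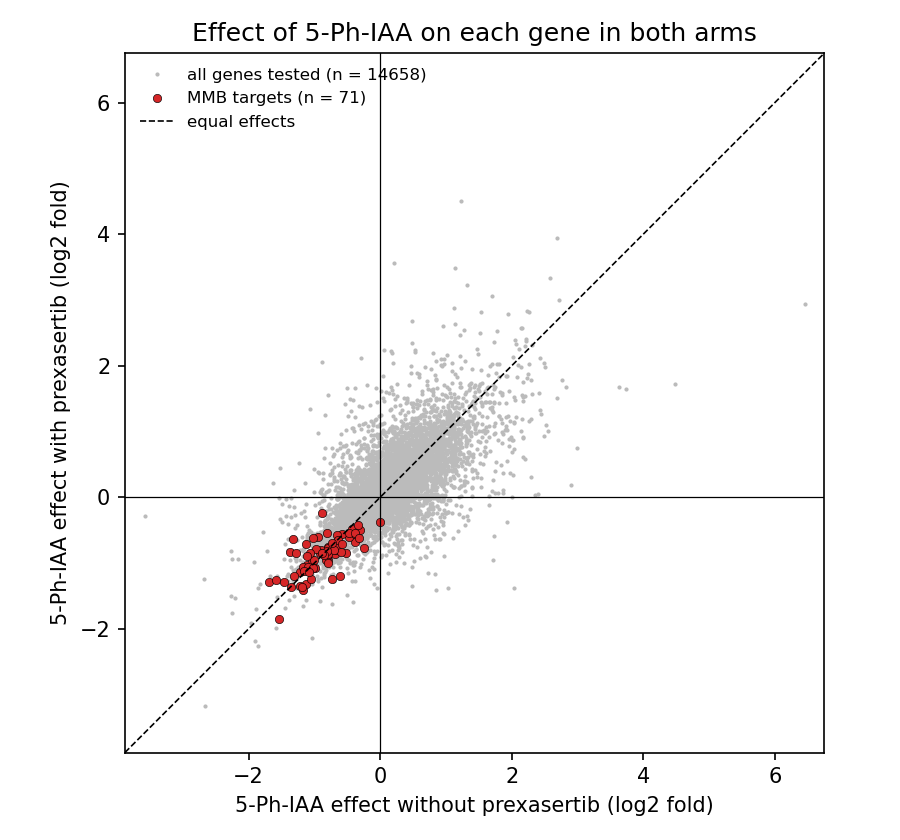
Log2 fold change of each of 14658 genes with 5-Ph-IAA, without prexasertib (x axis) and with it (y axis), with the 71 MMB targets in red and a dashed line of equal effects. The MMB targets lie in the lower left, with medians of -0.85 and -0.84.

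Both drugs against 5-Ph-IAA asks what prexasertib did with 5-Ph-IAA present. Mitotic genes rose from their lower level: 42 of 71 MMB targets were higher and 0 were lower (59 and 0 adjusted over the list alone), with a median of 0.53. KIF20A rose from 67 ± 1.89 to 200.2 ± 2.66 CPM, a log2 fold change of 1.58 ± 0.06 (SE). UBE2C, the ubiquitin-conjugating enzyme of the anaphase-promoting complex, rose by 0.93 ± 0.074, CCNB1 by 1.12 ± 0.088 and PLK1 by 0.94 ± 0.087. The edgeR adjusted p-values were 8.5e-09, 2.9e-05, 2.9e-05 and 4.7e-05. The MMB list had camera adjusted p = 1.36e-54, and adjusted p = 0.00015 with an estimated correlation.

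p53 targets rose in 15 of 28 members and fell in 0 (23 and 1 adjusted over the list alone; 25 and 1 with the replicate block), with a median of 0.47, camera adjusted p = 2.07e-24 and 0.015 with an estimated correlation. CDKN1A rose from 1008 ± 57.9 to 1709 ± 90.6 CPM (0.76 ± 0.084), AEN by 0.74 ± 0.059 and BTG2 by 1.20 ± 0.11. E2F targets had 14 lower members and 1 higher (21 and 1 adjusted over the list alone), with a median of -0.28, camera adjusted p = 7.49e-14 and adjusted p = 0.19 with an estimated correlation (0.042 with the replicate block as well). UHRF1 fell by 0.82 ± 0.093, the replication factor gene MCM10 by 0.80 ± 0.1, and PCNA rose by 0.36 ± 0.077. Leaving out 5-Ph-IAA replicate 1 or 2, or replicate 1 or 2 of both drugs, moved the count of lower E2F targets to as few as 7 and that of higher immediate-early genes to as few as 2. DNA repair genes had 4 lower members (7 adjusted over the list alone; 12 with the replicate block), with a median of -0.26, camera adjusted p = 1.64e-08 and 0.0034 with an estimated correlation. BARD1 fell by 0.92 ± 0.12 and BRCA1 by 0.44 ± 0.065, with BLM and TOPBP1 as the others.

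Histone genes H2BC12 (0.56 ± 0.11), H3C10 (1.19 ± 0.26) and H2BC5 rose, 3 of 18 (6 adjusted over the list alone; 7 with the replicate block), with a median of 0.54, camera adjusted p = 9.52e-07 and 0.015 with an estimated correlation (0.069 with the replicate block as well). Immediate-early genes had 4 higher and 3 lower members (11 and 5 adjusted over the list alone; 13 and 5 with the replicate block). Their median was 0.37 with camera adjusted p = 0.0193, against 0.55 with an estimated correlation and 0.0641 without replicate 1 of both drugs. NR4A1 (0.69 ± 0.094), IER5 (0.47 ± 0.079), EGR1 and HBEGF rose, and CCN1 (-0.46 ± 0.071), KLF6 and MYC fell. MYC went from 112 ± 12 to 74.1 ± 2.91 CPM (-0.60 ± 0.1, edgeR adjusted p = 0.0057). ATF4 (0.38 ± 0.072) and DDIT4 (0.59 ± 0.11) rose and STC2 (-0.55 ± 0.081) and SLC7A11 fell in the ATF4 list (camera adjusted p = 0.593). Ribosomal proteins had 37 positive values of 37 and a median of 0.16, with 0 genes called by edgeR, DESeq2 and limma-voom, 1 at an unadjusted p under 0.05, and 26 higher with the replicate block. Camera gave them adjusted p = 1.47e-05, and 0.85 with an estimated correlation. In the remaining lists WEE1 (0.60), BRD8 (0.52) and IRF1 (0.33) rose and EPC2 (-0.57) fell. RBL1 fell as well, from 44.47 ± 0.914 to 25.55 ± 1.13 CPM. In these lists camera adjusted p lay between 0.0648 (MYC targets, 0.011 with the replicate block, against 0.087 with the block and an estimated correlation) and 0.974. The MYC-target list also passed without 5-Ph-IAA replicate 3 (0.00255) or replicate 1 (0.0169) or 2 (0.0157) of both drugs, and the sterol list without replicate 3 of both drugs (0.00236), while with an estimated correlation on all libraries each had 0.86. CHEK1 had a value of -0.34 ± 0.09 (edgeR adjusted p = 0.07, and 0.0062 with the replicate block). TRRAP (-0.16 ± 0.14), MYBL2 (-0.04 ± 0.16), LIN9 (-0.21 ± 0.13) and FOXM1 (0.07 ± 0.091) were not called, with edgeR adjusted p between 0.55 and 0.95. TRRAP was called without the libraries numbered 3 (-0.393, edgeR adjusted p = 0.00041). In number 3 itself it went the other way, with 141 CPM with both drugs against 119 CPM with 5-Ph-IAA.

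Over all genes, edgeR called 171 higher and 184 lower, DESeq2 312 and 345, and edgeR with the replicate block 1144 and 1128. Without the libraries numbered 3 the counts were 901 and 1121, and 88.6% of those calls had the same sign in the libraries numbered 3. Leaving out 5-Ph-IAA replicate 1 gave the lowest counts, 102 higher and 54 lower. 5-Ph-IAA replicate 2 moved both counts by more than 1.5 times, and replicates 1 and 2 of both drugs the lower count. With library size as the only scaling 31.6% of calls were higher instead of 48.2%. PCNA and H3C10 lost their calls without any 1 of 5 libraries (edgeR adjusted p up to 0.14 and 0.12), and ATF4, H2BC12 and DDIT4 without 2, 2 and 1. Across genes, the effects of prexasertib with and without 5-Ph-IAA correlated with Pearson's r of 0.511 and Spearman's rho of 0.489 (r = 0.104 without the low-count filter and 0.681 at 5 CPM or more). Of the called genes 133 were higher in both arms, against 4.04 by chance, 119 were lower in both, against 4.36 by chance, and 0 had opposite directions.

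**Figure D3:**
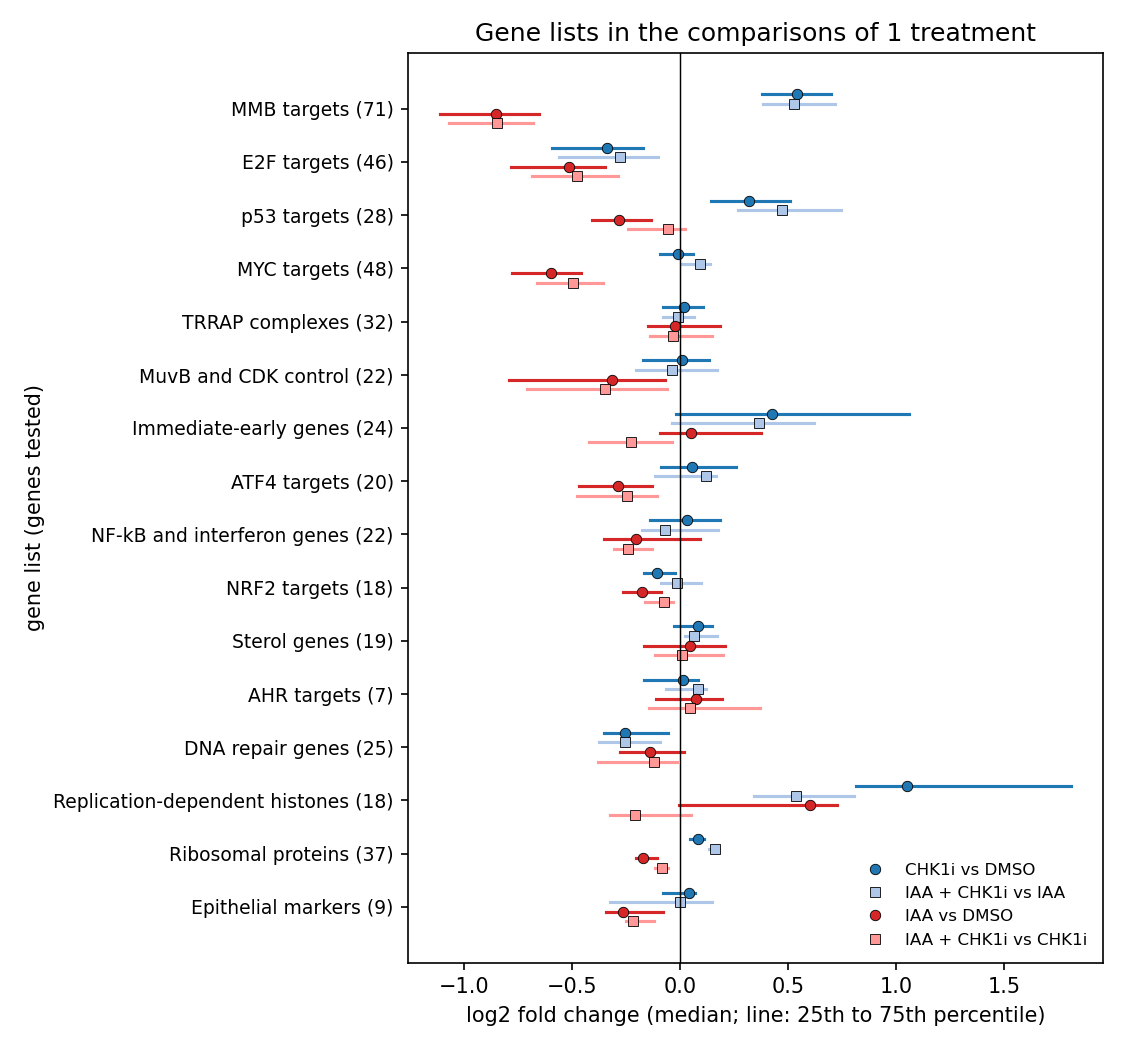
Median log2 fold change of each gene list (points) with the line from the 25th to the 75th percentile of its genes, for prexasertib (blue) and 5-Ph-IAA (red), each without (circles) and with (squares) the other drug. MMB targets had medians of 0.54 and 0.53 with prexasertib and of -0.85 and -0.84 with 5-Ph-IAA, and library size as the only scaling kept these signs.

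The interaction asks whether the effects of the 2 drugs added up on the log scale. For MMB targets the median interaction was -0.02 (camera adjusted p = 0.902), with 31 of 71 members positive. CCNB1 had an interaction of 0.42 ± 0.12 and PLK1 of 0.42 ± 0.12 (SE, edgeR adjusted p = 1 for each). CDKN1A had 0.34 ± 0.12 and MYC -0.53 ± 0.14 (edgeR adjusted p = 1 for each). TRRAP, MYBL2, LIN9, FOXM1 and CHEK1 had -0.01 ± 0.2, 0.06 ± 0.23, -0.24 ± 0.18, -0.06 ± 0.13 and -0.24 ± 0.13. The TRRAP interaction was -0.446 without the libraries numbered 3 (edgeR adjusted p = 0.039). In number 3 TRRAP went the other way. There it had 94.5 CPM in DMSO and 63.6 CPM with prexasertib, but 119 CPM with 5-Ph-IAA and 141 CPM with both drugs. With the replicate block CCNB1, PLK1, CDKN1A and MYC were called (edgeR adjusted p = 0.00072, 0.0007, 0.0022 and 0.018), and 8 MMB targets were higher and 2 lower. The ribosomal list then had camera adjusted p = 0.0027 (0.109 without the block, and 0.85 with the block and an estimated correlation). It also passed without DMSO replicate 2 (0.00305), prexasertib replicate 3 (0.000838), 5-Ph-IAA replicate 3 (1.02e-06), replicate 1 (0.00166) or 2 (0.0448) of both drugs, or all libraries numbered 3 (0.0001), and with limma-voom (0.0462). Over all genes edgeR called 0, with 519 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.152. DESeq2 called 5, limma-voom 0, and edgeR with the replicate block 55 higher and 41 lower. Without the libraries numbered 3 edgeR called 90 and 94, and 71.2% of those had the same sign in the libraries numbered 3. Over all genes the interaction without number 3 and that of number 3 alone correlated at r = 0.0289.

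**Figure D4:**
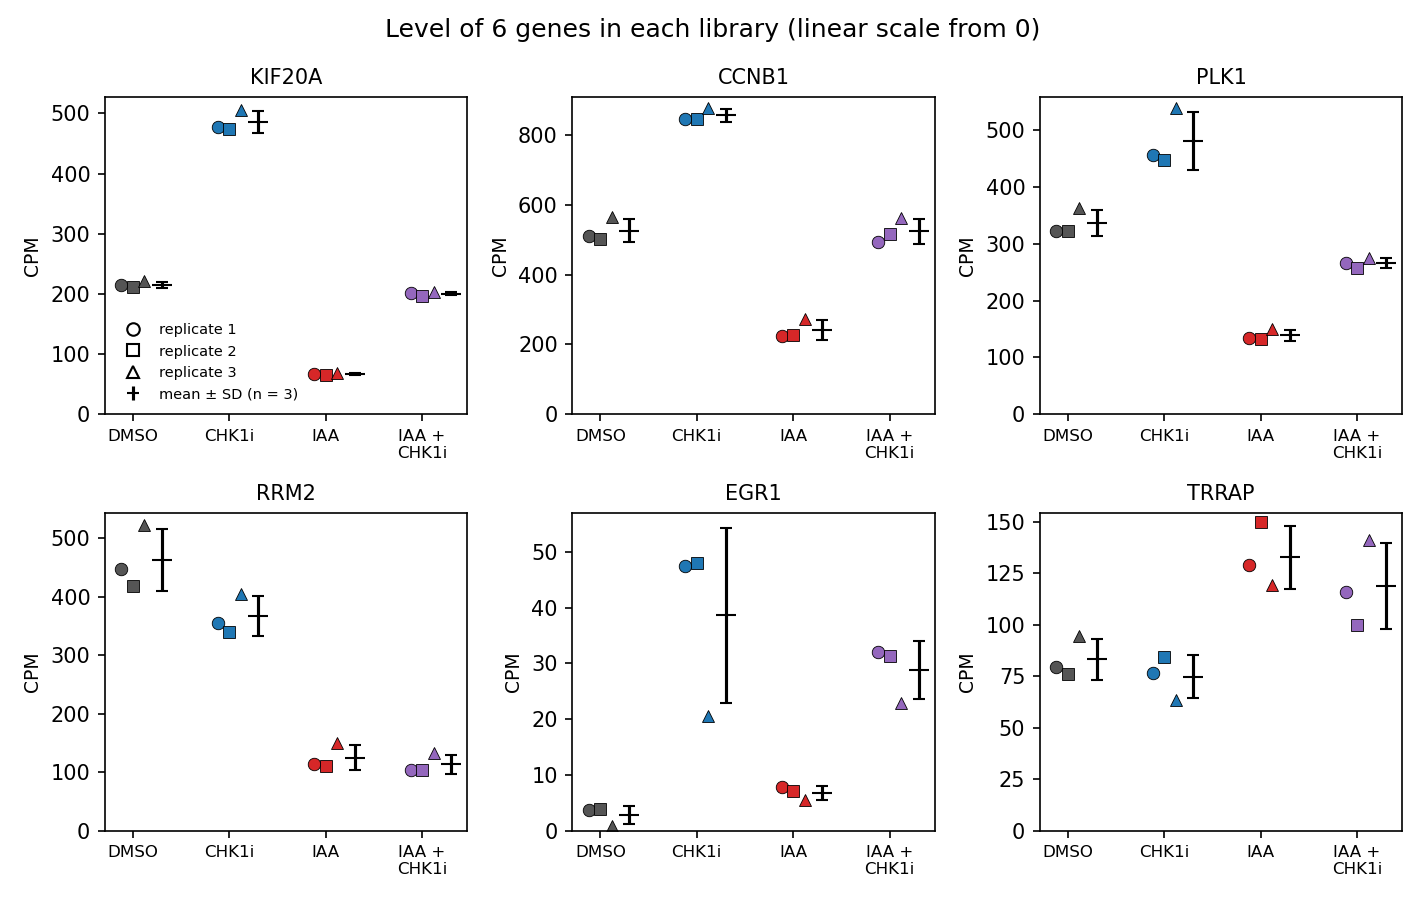
Level in CPM (linear axis from 0) of 6 genes in each library, with the mean and SD of the 3 libraries of a group (CHK1i marks prexasertib and IAA marks 5-Ph-IAA). CCNB1 has 526 CPM in DMSO and 524 CPM with both drugs, between 856 CPM with prexasertib and 241 CPM with 5-Ph-IAA, while RRM2 has 125 and 113 CPM in the groups with 5-Ph-IAA against 462 CPM in DMSO.

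Both drugs against DMSO gives, on the log scale, the 2 single effects plus their interaction. MMB targets were lower in 43 of 71 members and higher in 3, NEK2, CKAP2 and DEPDC1 (47 and 3 adjusted over the list alone), with a median of -0.36. Without DMSO replicate 3 or replicate 2 of both drugs 1 or 2 of these 3 were called. Camera gave adjusted p = 2.22e-11 for MMB targets, and 0.016 with an estimated correlation. E2F targets were lower in 38 of 46 members (40 adjusted over the list alone), with a median of -0.86, camera adjusted p = 1.76e-21 and adjusted p = 0.077 with an estimated correlation (0.014 with the replicate block as well). MYC targets were lower in 32 of 48 (39 adjusted over the list alone), with a median of -0.52, camera adjusted p = 1.82e-14 and adjusted p = 0.091 with an estimated correlation (0.0025 with the replicate block as well). MuvB and CDK control genes were lower in 14 of 22 and higher in 1, CHEK2 (17 and 1 adjusted over the list alone; camera adjusted p = 7.55e-06, and 0.016 with an estimated correlation). DNA repair genes were lower in 14 of 25 (15 adjusted over the list alone; camera adjusted p = 2.48e-06, and 0.016 with an estimated correlation). Histones were higher in 11 of 18 with a median of 1.22 (13 adjusted over the list alone; camera adjusted p = 1.39e-06, 0.016 with an estimated correlation, and 0.051 with the replicate block as well). p53 targets were higher in 10 of 28 and lower in 3, TP53I3, ZMAT3 and TIGAR (11 and 3 adjusted over the list alone; 19 and 3 with the replicate block; camera adjusted p = 0.000732, and 0.35 with an estimated correlation). ATF4 and NRF2 targets were lower in 7 of 20 and 5 of 18, with camera adjusted p = 0.00632 and 0.00743, and 0.1 and 0.12 with an estimated correlation. Without any 1 replicate of both drugs, or DMSO replicate 1 or 2, the lower NRF2 targets fell to as few as 3, and the replicate block gave 12. The other lists gave camera adjusted p between 0.0798 (immediate-early genes, 0.0431 without replicate 3 of both drugs and 0.0485 with the replicate block, against 0.54 with an estimated correlation and 0.55 with the block as well) and 0.935. TRRAP rose by 0.51 ± 0.14 (edgeR adjusted p = 0.016, and 0.06 with the replicate block). Over all genes, edgeR called 1725 higher and 2077 lower, and 3111 and 3441 with the replicate block. Of the calls without the libraries numbered 3, 95.4% had the same sign in the libraries numbered 3. With library size as the only scaling the median of all genes was 0.11 higher, and 65.2% of calls were higher instead of 45.4%.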

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

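The splits of the library pairs and the tests of the weakly expressed genes were chosen after the results were seen, the first after another scheme of splits had been run and set aside as flawed. The gene lists below passed camera with the preset correlation in the interaction, with edgeR calling 0 single genes of each in the fit on groups. Fry gave adjusted p = 0.53 for p53 targets, 0.95 for MYC targets, 0.69 for immediate-early genes and 0.033 for histones. Only the histones thus passed fry and camera with an estimated correlation as well. The unadjusted p was under 0.05 for 4 p53 targets, 1 MYC target, 5 immediate-early genes and 6 histones, DESeq2 called 2, 0, 0 and 0, and limma-voom 0 in each. The p53 targets had a median interaction of 0.184 (camera adjusted p = 2.49e-06, and adjusted p = 0.45 with an estimated correlation). The MYC targets had a median of 0.079 (camera adjusted p = 0.0421, and adjusted p = 0.95 with an estimated correlation), and their call was lost without DMSO replicate 3 (0.676), prexasertib replicate 1 (0.241) or 2 (0.425), 5-Ph-IAA replicate 1 (0.16) or 2 (0.645), or replicate 3 of both drugs (0.585). The immediate-early genes had a median of -0.236 (camera adjusted p = 0.000792, and adjusted p = 0.45 with an estimated correlation). The replication-dependent histones had a median of -0.605 (camera adjusted p = 1.6e-08, and 0.021 with an estimated correlation, against 0.13 with the replicate block as well).

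The interaction with the replicate block differed between the arms for 96 genes, 55 higher and 41 lower. Among MMB targets the ubiquitin-conjugating enzyme gene UBE2C had 0.69 ± 0.077 (SE, edgeR adjusted p = 8.6e-08), the mitotic kinase gene CDK1 had 0.65 ± 0.087 and the kinetochore motor gene CENPE had -0.49 ± 0.1. The p53 targets PHLDA3 and AEN had 0.55 ± 0.075 and 0.47 ± 0.072. EGR1 had -1.67 ± 0.27, FOSB -1.81 ± 0.36 and WNT6 1.55 ± 0.26. The median gene span was 8.53 kb for the higher genes, 35.7 kb for the lower genes and 28.7 kb for all genes tested.

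For these 96 genes a gene length trend and a difference in depth were weighed as technical explanations against an interaction of the drugs. After a smooth trend on gene span was removed from each library, 58 of the 96 genes were still called. The medians of the 96, which were chosen by their calls, went from 0.446 to 0.414 for the higher and from -0.467 to -0.466 for the lower genes. Over all genes, Spearman's rho between gene span and the interaction was -0.176 before and 0.00787 after the removal. With the trend removed fewer genes were called higher than lower, as counted below, against 55 and 41 before. These values argue against a trend on gene span as the whole source, but some of the higher calls depended on it. After thinning to the shallowest library 73 were still called, which argues against depth as the whole source. With the library pairs as blocks 170 genes were called, against at most 14 in the other splits of the 6 pairs. The real split was the 1 of 10 splits that gave as many, and 10 splits cannot give a share under 0.05. The other splits mix pairs of both arms, which adds any difference between the arms to the spread, so their low counts are no support. Which biological process the interaction may reflect was not tested.

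The histone rise with prexasertib (median 1.05) was weighed against carryover of RNA without poly(A) tails and against a gene length trend. The 3631 other genes in the span quartile of the histones had a median of 0.016. This argues against a trend shared by the genes of that quartile as the whole source. A trend confined to the very shortest genes was not tested. The span includes introns, so a trend on the length of the mRNA was not tested either. The other 37 RNAs without poly(A) tails had a median of 0.195, with a 95% bootstrap interval over these RNAs from -0.173 to 0.284. However, 31 of them are small nucleolar RNAs, whose reads can belong to the host RNA. Outside those, only RN7SL1 (0.23) and RN7SL2 (0.118) reached a mean of 5 CPM, while RN7SK (1.64, edgeR adjusted p = 0.21) and RMRP (0.936, edgeR adjusted p = 0.64) had higher values under 1 CPM. The bound set on that median before the test was therefore no measure of carryover. Carryover and a change in the level or in the polyadenylation of histone mRNA with prexasertib cannot be told apart, because too few other RNAs of this kind were measured above the floor. Reads shared between histone paralogs were not tested.

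Among genes with a mean under 1 CPM, 68 were higher and 6 were lower with 5-Ph-IAA, while at 100 CPM or more 82 were higher and 616 were lower. The 68 genes were chosen by their calls against DMSO, so they were tested in both drugs against prexasertib, which shares no library with that comparison. The count filter, the limit of 1 CPM and the estimate of the spread used all 12 libraries, however. That arm is therefore not fully independent of the choice. There their median was 1.23 (95% bootstrap interval over genes 1.09 to 1.53), and 67 were positive. The summed reads of 486 silent receptor and keratin-associated genes had a log2 ratio of 0.17 in that arm (95% interval -0.057 to 0.41). The intervals of silent genes, here and below, come from Poisson resampling of the summed reads. Of these genes 4 passed the filter and 1 held 29.6% of the reads. Without the 4 genes the ratio was 0.23 (-0.11 to 0.58), without the libraries numbered 3 it was -0.0073 (-0.28 to 0.27), and without both it was 0.23 (-0.18 to 0.64), while the 68 genes had a median of 1.34 (0.968 to 1.53) without the libraries numbered 3. The pair numbered 3 alone gave 0.67 (0.22 to 1.1). The log2 ratio of the scaling factors in that arm was 0.14. The ratios over 2 or 3 pairs and the scaling ratio lie below the interval of the 68 genes, which argues against uniform background reads or scaling as the whole source of those calls. Neither kind of interval measures the spread between libraries, and the pairs numbered 1 and 2 gave -0.12 and 0.13. For the pair numbered 3 alone the upper end of 1.1 reaches the interval of the 68 genes, so background stays open there.

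The shift of all 1015 genes under 1 CPM was weighed apart from those calls, with medians of 0.449 without and 0.453 with prexasertib. Background reads and a wider change of expression cannot be told apart for it, because the reads of the silent genes are few and their ratio depends on which are counted. Without prexasertib the 486 silent genes gave 0.33 (95% interval 0.12 to 0.55), which includes the median, but the pair numbered 3 gave 0.74 against 0.2 and 0.12 for the other pairs, and without number 3 the ratio was 0.17 (-0.085 to 0.42), below the median of 0.446. The 482 silent genes below the filter gave 0.55 (0.22 to 0.89), and 0.46 (0.079 to 0.86) without number 3, which include the medians. With prexasertib all 486 gave 0.17, below the median, and the 482 gave 0.23 with an interval that includes it. The shift may therefore hold some background.

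Other splits of the libraries were counted for the calls over all genes. The real splits gave 693 calls for prexasertib against DMSO, 3201 for 5-Ph-IAA against DMSO, 2674 for both drugs against prexasertib, 355 for both drugs against 5-Ph-IAA and 3802 for both drugs against DMSO. In each of these 1 of 10 splits, the real one, gave as many calls, and the highest other split gave 0. Of the 4 splits that part all 3 pairs of replicate numbers, the highest besides the real one also gave 0, and the other splits part fewer pairs. For the interaction in the fit on groups all 10 of 10 splits gave 0 calls. Splits as few as 10 cannot give a share under 0.05. The other splits also mix libraries of the groups compared, which adds any difference between the groups to the spread within them. Their low counts are therefore no support for the calls.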

How the results depend on the processing

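The fits without the libraries numbered 3, with a gene span trend removed and after thinning, and list tests with the block and an estimated correlation together, were chosen after seeing the data. No value changed its direction past the threshold. Where a count moved by more than 1.5 times, the cause was not tested, apart from a minimum fold change, which lowers counts by construction. Leaving out libraries moved counts both up and down. Higher and lower genes are given in that order, for prexasertib against DMSO, 5-Ph-IAA against DMSO, both drugs against prexasertib, both drugs against 5-Ph-IAA, the interaction, and both drugs against DMSO.

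With the replicate block the numbers treat the samples as paired, and edgeR called 1227 and 1432, 2780 and 3465, 2528 and 2913, 1144 and 1128, 55 and 41, and 3111 and 3441. MMB targets then had 2 lower genes for prexasertib against DMSO and 8 and 2 in the interaction. The blocked interaction had 29 and 35 genes with a span trend removed and 45 and 32 after thinning. Without the libraries numbered 3 the counts were 1060 and 1030, 2459 and 2824, 1933 and 2559, 901 and 1121, and 90 and 94. MMB targets then had 2 lower genes for prexasertib against DMSO, 1 lower for both drugs against 5-Ph-IAA, and 9 and 2 in the interaction. TRRAP was then called lower for both drugs against 5-Ph-IAA (-0.393, edgeR adjusted p = 0.00041) and in the interaction (-0.446, edgeR adjusted p = 0.039), while the libraries numbered 3 went the other way in each. MYC was called lower for both drugs against prexasertib (-0.258, edgeR adjusted p = 0.012), and CHEK1 with 5-Ph-IAA lost its call (-0.212, edgeR adjusted p = 0.093). The effect correlations then were 0.64 for 5-Ph-IAA and 0.397 for prexasertib. With a log2 fold change of at least 1 the counts were 54 and 25, 297 and 136, 235 and 97, 24 and 6, and, for both drugs against DMSO, 436 and 173. MMB targets then had 2 higher, 27 lower, 22 lower and 3 higher genes in the first 4 comparisons, and edgeR called 0 higher and 0 lower for both drugs against DMSO.

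With library size as the only scaling, 3018 and 986 genes were called with 5-Ph-IAA, 2569 and 889 under prexasertib, 335 lower for both drugs against 5-Ph-IAA, 1 higher in the interaction (an MMB target, 1 higher), and 2696 higher for both drugs against DMSO. DESeq2 called 312 and 345 for both drugs against 5-Ph-IAA and 5 higher in the interaction, 2 of them MMB targets. Only the groups compared gave 205 and 152 for prexasertib against DMSO and 64 lower for both drugs against 5-Ph-IAA, and correlations of 0.785 and 0.587. Without a filter the correlations were 0.231 and 0.104, and with the strict filter 0.852 and 0.681.

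Leaving out 1 library gave 183 to 385 higher and 123 to 401 lower genes for prexasertib against DMSO, 844 to 1604 higher for 5-Ph-IAA against DMSO, 692 to 1225 higher for both drugs against prexasertib, and 102 to 202 higher and 54 to 245 lower for both drugs against 5-Ph-IAA. The higher MMB targets for both drugs against DMSO numbered 1 to 3, fewest without DMSO replicate 3 or replicate 2 of both drugs. The correlations ranged from 0.641 to 0.702 and from 0.416 to 0.469, all below the 0.739 and 0.511 of all libraries. The count filter was run again in each of these fits, so the genes tested could differ. Since the correlations depend on the filter, the drop cannot be assigned to the library left out. The counts over all genes moved by more than 1.5 times without DMSO replicates 1, 2 or 3, or replicates 1 or 2 of the other groups, in some of the comparisons that hold them. Counts of single lists also moved without other libraries, as given above. Depth limits the genes under 1 CPM, and DESeq2 gave no adjusted p for 1425 genes in either prexasertib comparison.

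Single genes lost their calls under other choices as well. For prexasertib against DMSO, only the groups compared left FOSB (0.088), CCDC183-AS1 (0.057), PPARGC1B (0.069), PCNA (0.054), BRCA1 (0.057) and MDC1 (0.074) without a call, library size as the only scaling MDC1 (0.057), limma-voom FOSB (0.13) and CCDC183-AS1 (0.062), no filter FOSB (0.091) and LAG3 (0.052), and the fit without the libraries numbered 3 PPARGC1B (0.053). With 5-Ph-IAA, NBN had 0.11 without a filter. Under prexasertib, BTG2 lost its call with library size as the only scaling (0.058), while CDKN1A gained one (0.322, adjusted p = 0.023). For both drugs against 5-Ph-IAA, only the groups compared gave 0.073 for PCNA, 0.072 for ATF4 and 0.058 for H3C10, and CHEK1 was called with library size as the only scaling (0.029) and by DESeq2 (0.039). The values in this paragraph are adjusted p-values of the fit named, edgeR unless another tool is given.

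List tests changed too. Without the libraries numbered 3 camera passed NRF2 targets (0.0327) for prexasertib against DMSO, epithelial markers (0.0217) for 5-Ph-IAA against DMSO, and immediate-early (0.00173), NF-kB and interferon, ribosomal and epithelial lists (0.0132 each) for both drugs against prexasertib. It then also passed MYC targets (0.0478) and sterol genes (0.0302) for both drugs against 5-Ph-IAA, NRF2 targets (0.0226) and DNA repair genes (0.0209) in the interaction, and immediate-early genes (0.00878) for both drugs against DMSO. DNA repair genes with 5-Ph-IAA (0.207) and MYC targets in the interaction (0.0509) no longer passed. The strict filter gave 0.111 for DNA repair genes with 5-Ph-IAA. Without a filter p53 targets (0.0404), NRF2 targets (0.0393), and NF-kB and interferon and ribosomal lists (0.0346 each) passed for both drugs against prexasertib, and MYC targets had 0.0597 in the interaction. E2F targets passed in the interaction without prexasertib replicate 3 (0.0341), sterol genes for prexasertib against DMSO without the same library (0.0262), and epithelial markers with 5-Ph-IAA without DMSO replicate 3 (0.047). With an estimated correlation on all libraries, the lists that passed only under these choices had adjusted p between 0.45 and 0.95. The values above are camera adjusted p-values. Fry matched the main camera test in 82 list tests, lost 7 and gained 1, immediate-early genes for both drugs against DMSO (fry adjusted p = 0.026). Lost were ribosomal proteins for prexasertib (0.86) or 5-Ph-IAA (0.28) against DMSO and for both drugs against 5-Ph-IAA (0.51), and immediate-early genes in the last (0.25). In the interaction fry lost p53 targets (0.53), MYC targets (0.95) and immediate-early genes (0.69).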

Other observations

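The test of the small nucleolar RNA host genes as a group was chosen after their values were seen. These host genes (SNHG genes, GAS5 and ZFAS1) carry small nucleolar RNAs, which guide the modification of ribosomal RNA, in their introns. With 5-Ph-IAA, 14 of 23 were lower and 0 were higher by edgeR, with a median of -0.64, and 11 were lower under prexasertib, with a median of -0.59. SNHG7 fell by 1.40 ± 0.11 (SE), SNHG1 fell by 1.28 ± 0.19, SNHG16 fell by 0.84 ± 0.089 and GAS5 fell by 0.64 ± 0.15. Of the 31 genes for small nucleolar RNAs tested, 6 were lower with 5-Ph-IAA, with a median of -1.08. The summed reads of the hosts were at least 25 times those of the small nucleolar RNA genes in each of the 12 libraries. SNHG29 (mean 514 CPM) and SNHG5 (199 CPM), which were not called, weigh most in that sum. For weaker hosts such as SNHG15 (9.56 CPM) the ratio cannot tell whether reads of small nucleolar RNAs contributed. As a set the hosts were lower than other genes in both backgrounds (camera with an estimated correlation, p = 0.016 and 0.021). That the hosts fall as a group is a hypothesis found and tested on the same data.

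The libraries numbered 3 differed from those numbered 1 and 2 at 3311 genes that were higher and 3135 that were lower by edgeR with the groups as a term, whereas numbers 2 and 1 differed at 5 and 10. CEACAM6, an epithelial adhesion gene, had a log2 value of -3.32 in number 3. Ribosomal proteins were higher in number 3 in 35 of 37 members, sterol genes were lower in 15 of 19, and epithelial markers were lower in 7 of 9. The counts of pairs of libraries of a group had a chi-square per degree of freedom of 2.2 to 3.81 for numbers 1 and 2 and of 12.3 to 18.3 with number 3.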
